A study of Mus musculus with 15 samples.

How the data were processed

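RNA of mouse tumours collected from the frontal cortex was extracted with the Qiagen RNeasy kit and made into TruSeq mRNA libraries, per the labels' protocols. The 15 libraries were grouped by the genotype and histone given in the labels. Per the submitters' processing notes, the tools were STAR 2.7, HTSeq and DESeq2 on the mm10 build. The versions of HTSeq and DESeq2, their settings, the strand setting and the annotation are not given in the sources used here. The deposited data are 5 tables of 54232 genes, one for each pair of groups compared by the authors. Their columns for single libraries hold a signal that the authors made by dividing the read count of each gene by 1 size factor per library, set within each table's libraries. Per the file headers a further column holds the mean of that signal. Per the file headers, the authors also deposited a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value from DESeq2. Every library value was a whole multiple of the value of 1 read (100% of values within 0.01), and a library had the same reads in each table, so the reads of every gene were recovered by division. In 3 columns the value of 1 read lay near 1, and those columns were not used for this. Libraries held 22807315 to 35679129 reads in genes.

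Because the deposited values are normalized, the test fixed for that case before the data were examined was used. Each pair of groups was fitted alone with limma 3.58.1 (trend and robust options) in R 4.3.3 on log2 of the table's value plus a pseudocount of 1, for genes with a mean of at least 10, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The pseudocount understates the log2 change of genes with few counts. The interaction was fitted on all 15 libraries after scaling the recovered reads together by the median of ratios. Tables were read with the data.table package (version 1.17.8). Means and SDs of groups use each table's own values, and values of single libraries are scaled over all 15. Ensembl gene IDs were matched to symbols and mm10 positions of GENCODE vM21, which may not be the annotation of the authors (54079 IDs, 99.7%). The Atrx difference over all libraries was tested by exact permutation.

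Before the data were examined, 33 lists of genes were written from general knowledge, of which 3 symbols had no match, and lists with at least 5 tested genes were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists. Its p-values assume nearly independent genes, so the adjusted p with the correlation estimated from the data is given beside each call. A member is also given a limma p-value adjusted over its list alone. Only members with a mean of at least 10 were tested. These were 7 to 9 of 39 listed Hox genes and 78 to 82 of 143 listed PRC2-bound regulators. A gene low in most libraries can reach that mean through the group where it is high. Genes named are, by a rule fixed before the data were examined, Atrx, Trp53, H3f3a, H3f3b and Pdgfa, up to 6 called genes in each direction with the smallest p whose groups do not overlap (predicted genes, pseudogenes and mitochondrial genes left out), and up to 4 members with the smallest p of each list described. Others are stated to have been chosen after their values were seen.

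Alternatives fixed before the data were examined were no filter on low values, pseudocounts of 0.5 and 5, DESeq2 1.42.0 and limma-voom with quality weights on the recovered reads, all 4 groups in 1 fit, libraries that share the first code of their title summed, log2 Xist as a covariate (the labels give no sex), an estimated correlation for lists and each library left out. TMM scaling was added after. The edgeR 4.0.16 quasi-likelihood test was named beforehand as an added alternative for normalized values. It is counted apart from the alternatives fixed before. A gene that was not called is compared between settings as a value, by whether its log2 change moved by at least its standard error in the reported analysis. Every other split of the libraries of a pair of groups was fitted with limma and with DESeq2, and 99 drawn regroupings beside the real one for the interaction with limma, to count calls by chance. Each fit was tested on simulated data drawn from the real means and spread, with 200 genes changed by known folds. Genes were drawn independently of each other, in 1 draw per comparison, with the spread of each gene as estimated by edgeR. The share of false DESeq2 calls in such data therefore need not be that in the real data. Libraries of a group were compared in pairs to look for the same material sequenced again, and the smallest chi-square per degree of freedom over 21 pairs was 91.3, where 1 is the value for repeated sequencing of the same library. No library and no deposited table was left out, and results that need genes withheld for evaluation are not reported here.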

Results

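RNA was sequenced in 15 libraries from mouse brain tumours. Tumours were started in the frontal cortex of C57BL/6 mice whose Nestin-expressing neural progenitors carry Tva, a receptor for avian viruses. Virus-producing chicken cells delivered the recombinase Cre, the growth factor PDGFA and a GFP-tagged histone H3.3, and tumours were collected at the functional end point. Cre acts on floxed Trp53 in every tumour, and on floxed Atrx, which encodes a chromatin remodeller that helps deposit H3.3, in 8 of them. The histone was wild type (H3.3WT) or carried the H3.3G34R substitution found in some human gliomas. The groups were Atrx-floxed with H3.3G34R (ATRXfl_G34R, n = 4), Atrx-floxed with H3.3WT (ATRXfl_WT, n = 4), Atrx-intact with H3.3G34R (p53_G34R, n = 3) and Atrx-intact with H3.3WT (p53_WT, n = 4). The series title names cooperation of H3.3G34R with Atrx loss in raising targets of the Polycomb complex PRC2, Notch signalling and neuronal lineage genes. Libraries held 22807315 to 35679129 reads in genes, with 22807315 to 27495222 in ATRXfl_G34R, 24022308 to 29976738 in ATRXfl_WT, 26329990 to 30574393 in p53_G34R and 24979735 to 35679129 in p53_WT. Each library is called a tumour here, although no label says that each came from a separate mouse, so p-values of single genes measure the spread between these libraries. Camera p-values set a list against the other genes instead and, at the preset correlation, assume nearly independent genes. Values are size-factor-normalized read counts as mean ± SD. Values of single libraries were scaled over all 15, so they differ slightly from those behind a comparison's means. For each list of genes described, edgeR called 0 members in every comparison, and where 0 members are given for limma the authors' deposited tables also hold 0 past the threshold unless their count is given. Of 87 list results that did not pass with every library in the fit, 62 passed when some 1 library was left out, and those libraries are named here for the Notch, Hox, PRC2-bound, neuronal fate and mature neuron lists.

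Atrx, the targeted gene (ENSMUSG00000031229; mm10 chromosome X, 105797615 to 105929403), was lower in each floxed tumour than in any intact one. It stood at 2376 ± 619 normalized counts (n = 8) against 6687 ± 1395 (n = 7), or 35.5% of the intact level. The log2 difference was -1.51 (SE 0.19; 2-sided exact permutation p = 0.000155 over 6435 splits, the smallest that they can give). Counts cover the whole gene and the deleted part is not given in the labels, so a residual level is not a measure of residual protein. Adjusted over the list of engineered genes alone, Atrx was lower in floxed tumours with H3.3G34R (adjusted p = 0.00589), with H3.3WT (0.000666) and in the comparison of both changes with neither (0.00204), while over all genes it did not pass limma (0.664, 0.238 and 0.480). Trp53, H3f3a, H3f3b and Pdgfa passed in none of the 5 comparisons by either adjustment.

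Single tumours stood apart in the transcripts of normal cortex. In p53_WT replicate 3, Snap25, a synaptic protein gene of mature neurons, was at 37984 and Mobp, a myelin gene, at 17439, against at most 869 and 662 in the other 3 tumours of that group. The same tumour held 1239 counts of Pdgfa, against at least 10267 in the other 3. ATRXfl_G34R replicate 3 held 3345 counts of Snap25 and 13536 of Mobp, and replicate 4 held 3912 of Mobp, against at most 131 of Mobp in replicates 1 and 2. Xist, which marks female cells, was at most 27.7 in 7 tumours and at least 10675 in the other 8, with both kinds in each group. The kinds were not evenly spread. The median of Xist was 17.3 in ATRXfl_G34R, 5349 in ATRXfl_WT, 21879 in p53_G34R and 23645 in p53_WT. Tumours with low Xist were thus more common in the floxed groups than in the intact ones, so sex was not balanced over Atrx status. Snap25, Mobp, Xist and the vesicle gene Syt1 were chosen as genes of single libraries after their values were seen.

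**Figure D1:**
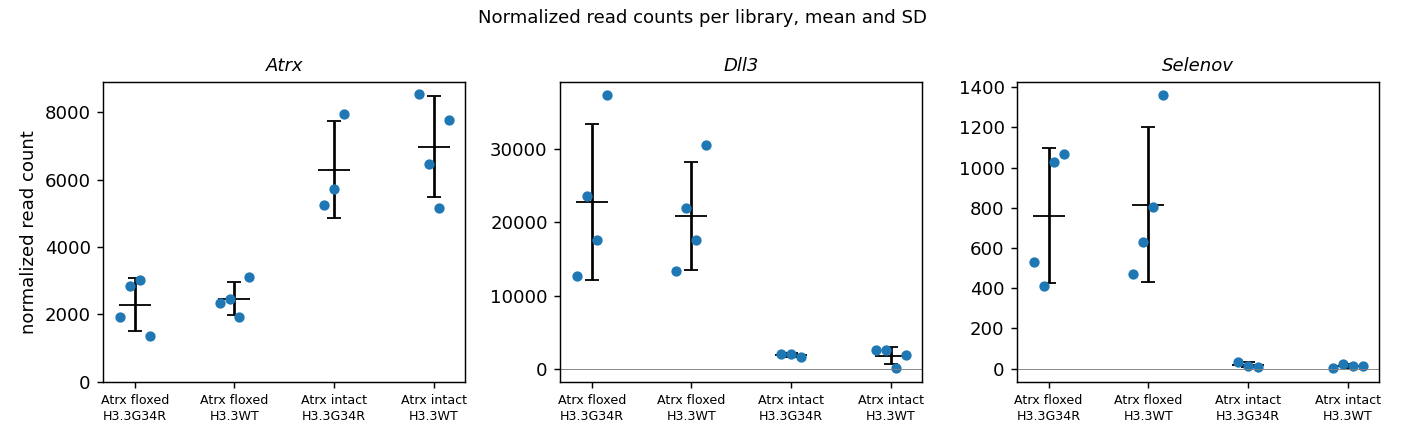
Normalized read counts of Atrx, Dll3 and Selenov (linear vertical axes) in each library, by group; points are libraries, bars are means and whiskers are 1 SD. Atrx spans 1346 to 3124 in the 8 floxed tumours and 5143 to 8540.0 in the 7 intact ones, and Dll3 and Selenov lie higher in each floxed tumour than in any intact one.

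Among Atrx-floxed tumours, H3.3G34R was compared with H3.3WT (n = 4 each) to ask what the mutant histone adds where Atrx is floxed. Of the mature neuron synapse genes, 21 of 25 had a positive log2 change (median 1.40), and of the neuronal fate and differentiation genes 30 of 38 did (median 0.39). Both lists rose by camera (adjusted p = 1.06e-07 and 4.6e-05), and neither call held with an estimated correlation (adjusted p = 0.852 with an estimated correlation for both). Nefm, a neurofilament chain, rose from 151 ± 38.8 to 743 ± 349.5 (log2 2.22 (SE 0.36)) and Rph3a, an effector of synaptic vesicles, rose from 36.8 ± 16.3 to 477 ± 471 (log2 3.26 (SE 0.67)). Each was the 1 member of its list past limma adjusted over the list alone (adjusted p = 0.00424 and 0.0180), and 0 members passed over all genes (adjusted p = 0.488 and 0.9997), where 7 fate genes and 5 synapse genes had an unadjusted p under 0.05. The authors' deposited table has 3 and 2 past the threshold. Other members had 198 ± 229 against 5.76 ± 3.76 for the neurofilament gene Nefl, 849.7 ± 661 against 206 ± 129.8 for the neuronal RNA-binding protein gene Celf4 and 1425 ± 1239 against 260.5 ± 180.1 for Snap25. ATRXfl_G34R replicate 3 held 2303 counts of the vesicle gene Syt1 against at most 322 in the other 3, and without it both lists still passed (0.00146 and 0.00764).

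Notch pathway genes fell as a list with H3.3G34R, with 28 of 36 negative (median -0.24, camera adjusted p = 0.00338, and adjusted p = 0.852 with an estimated correlation). The smallest p-values belonged to Ncstn, a subunit of the secretase that cleaves Notch (3420.3 ± 315 against 5812 ± 2287, log2 -0.70 (SE 0.25)), and the receptor Notch1 (4849.6 ± 1327 against 7163 ± 1183, log2 -0.59 (SE 0.24)). By limma, 0 members passed over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05). The Notch call was lost without ATRXfl_G34R replicate 4 (0.0581) or ATRXfl_WT replicate 1 (0.112). Hox cluster genes, which pattern the hindbrain and spinal cord and are known PRC2 targets, rose as a list, with 9 of 9 positive (median 1.30, adjusted p = 0.000600, and adjusted p = 0.852 with an estimated correlation). Hoxa4 stood at 354 ± 136 against 152 ± 72.5 and Hoxa5 at 710.4 ± 178 against 277 ± 197. Limma called 0 Hox genes by either adjustment (2 at an unadjusted p under 0.05). PRC2-bound developmental regulators outside the Hox clusters did not pass (35 of 79 positive, adjusted p = 0.484).

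Cell cycle genes rose as a list in Atrx-floxed H3.3G34R tumours (28 of 30 positive, median 0.53, adjusted p = 3.88e-05, and adjusted p = 0.852 with an estimated correlation), with the replication factor genes Mcm2 at 3312 ± 841 against 2202 ± 1163 and Pcna at 1698 ± 576 against 1167 ± 479. Mature oligodendrocyte genes (17 of 18 positive, 0.00414), antigen presentation genes (16 of 18, 0.0309) and immediate early and dissection stress genes (16 of 18, 0.00191) also rose, and endothelial genes fell (16 of 17 negative, 0.0410). Each of these last 4 lists had an adjusted p = 0.852 with an estimated correlation. By limma, 0 members of the 5 lists passed over all genes or adjusted over the list alone (0, 0, 0, 2 and 0 at an unadjusted p under 0.05). The cell cycle call was lost without ATRXfl_G34R replicate 4 (0.0572) or ATRXfl_WT replicate 1 (0.438), the oligodendrocyte call without ATRXfl_G34R replicate 3 (0.724), ATRXfl_G34R replicate 4 (0.0542) or ATRXfl_WT replicate 4 (0.0623) and the immediate early and dissection stress call without ATRXfl_G34R replicate 4 (0.0587) or ATRXfl_WT replicate 3 (0.0621). The antigen presentation call was lost without ATRXfl_G34R replicate 1 (0.0609), ATRXfl_G34R replicate 3 (0.449), ATRXfl_G34R replicate 4 (0.200), ATRXfl_WT replicate 1 (0.170) or ATRXfl_WT replicate 3 (0.727, direction turned), and the endothelial call without ATRXfl_G34R replicate 3 (0.173), ATRXfl_G34R replicate 4 (0.121) or ATRXfl_WT replicate 1 (0.211, direction turned). Oligodendrocyte progenitor genes, astrocyte genes, microglia and macrophage genes, ventral forebrain genes, dorsal forebrain genes, mural genes, erythroid genes, interferon genes and hypoxia genes did not pass (adjusted p = 0.493, 0.471, 0.906, 0.140, 0.407, 0.100, 0.230, 0.548 and 0.427).

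Gene by gene, limma called 0 of 17521 genes between H3.3G34R and H3.3WT with Atrx floxed, with 488 at an unadjusted p under 0.05 (282 higher, 206 lower), while edgeR called 0 and DESeq2 34. The authors' deposited table has 34 genes past the threshold, 29 higher and 5 lower. Of DESeq2 calls in simulated data of this comparison, 67 of 192 were false. Chosen after their values were seen, genes past the threshold in the authors' deposited table include Golga7b (log2 4.28, adjusted p = 9.04e-10), the vesicle gene Syt4 (2.15, adjusted p = 1.54e-07), the neurotrophic factor gene Gdnf (2.92, adjusted p = 6.86e-06) and the collagen gene Col12a1 (-2.65, adjusted p = 2.46e-08). In normalized counts Syt4 stood at 2306 ± 836 against 519 ± 86.3 and Col12a1 at 218 ± 70.2 against 1370.3 ± 556, each with groups that did not overlap (limma adjusted p = 0.146 and 0.146). Groups did not overlap for 2.16% of tested genes, where chance gives 2.86%. In simulated data of this comparison, limma recovered 77.3% of genes changed 8-fold, 55.2% of those changed 4-fold and 1.49% of those changed 2-fold.

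Among Atrx-intact tumours, H3.3G34R (n = 3) was compared with H3.3WT (n = 4), the effect of the mutant histone with Atrx present. Hypoxia and glycolysis genes rose as a list, with 17 of 17 positive (median log2 change 0.87, camera adjusted p = 3.02e-06, and adjusted p = 0.862 with an estimated correlation). Among them were Adm, a vasodilator peptide gene induced by low oxygen (2442 ± 638 against 671 ± 519, log2 2.24 (SE 0.68)), and Vegfa, an angiogenic factor gene (23719 ± 16509.5 against 8322 ± 7518, log2 1.78 (SE 0.77)). Mural and fibroblast genes rose as a list (14 of 17 positive, median 0.60, 0.000598, and adjusted p = 0.862 with an estimated correlation), with the collagen genes Col3a1 at 4469.7 ± 1974 against 1529 ± 972 and Col1a1 at 6131 ± 3081 against 2070 ± 1419. Limma called 0 members of both lists over all genes or adjusted over the list alone (3 and 3 at an unadjusted p under 0.05). The hypoxia call was lost without p53_G34R replicate 1 (0.312), and the mural call without p53_G34R replicate 3 (0.0517) or p53_WT replicate 4 (0.0981).

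Genes of normal cortical cell types fell as lists with H3.3G34R when Atrx was intact: 25 of 25 mature neuron genes were negative (median -1.11, adjusted p = 1.11e-05), 15 of 17 dorsal forebrain and excitatory lineage genes (-1.20, 0.00460) and 16 of 20 astrocyte genes (-0.98, 0.00345). With an estimated correlation each had an adjusted p = 0.862. Limma called 0 members over all genes or adjusted over the list alone (0, 0 and 2 at an unadjusted p under 0.05). The neuron call was lost without p53_WT replicate 3 (0.342), the dorsal call without p53_G34R replicate 1 (0.0692) or p53_WT replicate 3 (0.693) and the astrocyte call without p53_WT replicate 3 (0.576). Without p53_WT replicate 3 the medians were 0.04 for neuron genes (13 of 25 positive), -0.27 for dorsal genes (5 of 12) and -0.06 for astrocyte genes (10 of 20). The glutamate receptor gene Grin2b was at 11312 in p53_WT replicate 3 and at most 173 in the other 3 tumours, giving 31.3 ± 21.9 against 2950.1 ± 5657 for the groups. Id4, an inhibitor of differentiation in the astrocyte list, stood at 77.7 ± 18.6 against 418 ± 393 (log2 -2.05 (SE 0.65)), and Lhx2, a forebrain patterning gene in the PRC2-bound list, at 575 ± 158 against 1252 ± 146 (log2 -1.15 (SE 0.28)), neither past limma adjusted over its list alone (adjusted p = 0.262 and 0.248). Notch genes (23 of 36 positive, adjusted p = 0.100), Hox genes (7 of 7 positive, median 0.85, 0.273), PRC2-bound regulators (0.972), neuronal fate genes (0.172), oligodendrocyte progenitor genes (0.0664) and cell cycle genes (0.252) did not pass. The Notch list passed without p53_G34R replicate 1 (0.0121), the Hox list without p53_WT replicate 2 (0.000198) and the neuronal fate list without p53_G34R replicate 2 (0.0472) or p53_WT replicate 2 (0.0240). Without p53_WT replicate 3 the Hox median turned to -0.75 (2 of 7 positive, adjusted p = 0.396).

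Limma called 0 of 17873 genes for H3.3G34R with Atrx intact, with 262 at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 12. The authors' deposited table has 12 genes past the threshold, 7 higher and 5 lower. Of DESeq2 calls in simulated data of this comparison, 77 of 157 were false. Chosen after their values were seen, genes past the threshold in the authors' deposited table include the immunoglobulin genes Ighg2b (log2 6.81, adjusted p = 0.00119) and Igha (5.66, adjusted p = 0.00480), the collagenase gene Mmp13 (4.30, adjusted p = 0.00209) and the collagen gene Col5a2 (1.74, adjusted p = 0.0341). In normalized counts Mmp13 stood at 566 ± 499.9 against 28.7 ± 19.2, Col5a2 at 2204 ± 533 against 661 ± 212 and Igha, a product of plasma cells, at 4931 ± 7307 against 97.4 ± 61.6. Groups did not overlap for 2.61% of genes, where chance gives 5.71%. Limma recovered 5.97% of 4-fold and 33.3% of 8-fold changes in simulated data of this comparison.

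With H3.3G34R present, Atrx-floxed tumours (n = 4) were compared with Atrx-intact tumours (n = 3). Dll3, a Notch ligand of neural progenitors that inhibits the pathway, rose from 1877 ± 233 to 22762 ± 10614 normalized counts, a log2 change of 3.49 (SE 0.35). Selenov, a selenoprotein gene beside it, rose from 20.1 ± 12.3 to 759 ± 334 (log2 5.21 (SE 0.51)), and Adcy8, a calcium-stimulated adenylyl cyclase gene of neurons, rose from 48.5 ± 16.2 to 472 ± 64.7 (log2 3.29 (SE 0.32)). The limma adjusted p was 0.0334 for all 3, and each was higher in 4 of 4 floxed tumours than in any of the 3 intact ones. Dll3 and Adcy8 did not pass without any 1 of the 7 libraries (adjusted p = 0.0666 to 0.262 and 0.0530 to 0.262), and Selenov passed only without p53_G34R replicate 1 (0.0211, against 0.106 to 0.262 without any other). In mm10, Selenov (ENSMUSG00000046750) lies on chromosome 7, 28284652 to 28291186, Dll3 (ENSMUSG00000003436) on chromosome 7, 28293553 to 28302238 and Adcy8 (ENSMUSG00000022376) on chromosome 15, 64697084 to 64922296. Within 250 kb of Dll3, and chosen after their values were seen, the nucleolar methyltransferase gene Fbl was at 1217 ± 549 against 334 ± 3.49 and Eid2 at 2376 ± 407 against 1274 ± 273, with adjusted p of 0.364 and 0.989.

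With H3.3G34R, Hox cluster genes rose as a list in Atrx-floxed against Atrx-intact tumours. Of 9 tested members (39 listed), 8 were positive with a median log2 change of 2.57 (camera adjusted p = 3.36e-11, and adjusted p = 0.318 with an estimated correlation). The Hox members named in this report are all of the Hoxa cluster. Adjusted over the list alone, 6 passed limma, all higher, against 0 over all genes (6 at an unadjusted p under 0.05, and 5 past the threshold in the authors' deposited table). Hoxa5 rose from 90.6 ± 31.7 to 722 ± 179 (log2 3.01 (SE 0.35), list-alone adjusted p = 0.000183, 0.0537 over all genes), Hoxa3 rose from 79.7 ± 37.3 to 771 ± 285 (log2 3.33 (SE 0.44)) and Hoxa7 rose from 34.3 ± 17.2 to 625 ± 483 (log2 3.84 (SE 0.76)). PRC2-bound regulators outside the Hox clusters did not pass as a list (48 of 78 positive, adjusted p = 0.0571), and among them the hindbrain patterning gene Lmx1b was at 889 ± 234 against 315 ± 64.6 (log2 1.47 (SE 0.28), list-alone adjusted p = 0.0548). The authors' deposited table has 4 members of the PRC2-bound list past the threshold, Lmx1b among them (adjusted p = 0.00294). That list passed without ATRXfl_G34R replicate 3 (0.00232) or p53_G34R replicate 1 (0.00205).

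**Figure D2:**
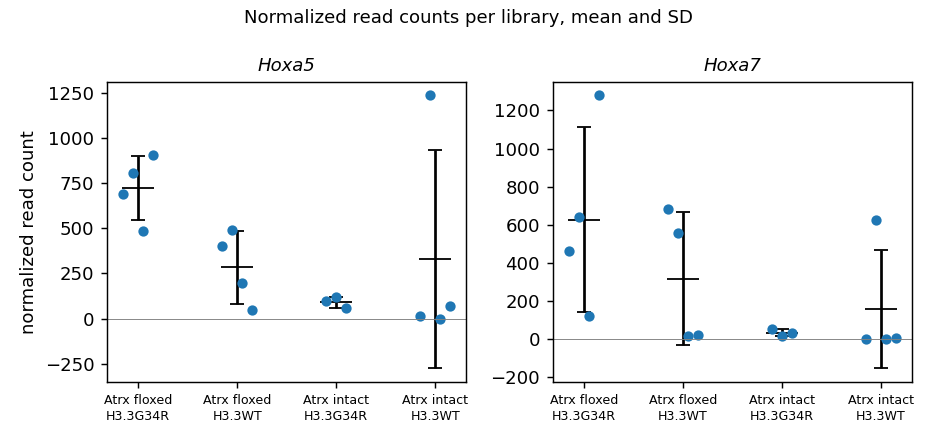
Normalized read counts of Hoxa5 and Hoxa7 (linear vertical axes) in each library, by group; points are libraries, bars are means and whiskers are 1 SD. Hoxa5 lies between 487 and 903 in the Atrx-floxed H3.3G34R tumours, and its highest single value, 1234, belongs to 1 Atrx-intact H3.3WT tumour.

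Notch genes did not pass as a list for Atrx status in H3.3G34R tumours (18 of 36 positive, adjusted p = 0.461), and Dll3 was the 1 member past limma both over all genes and adjusted over the list alone (adjusted p = 0.000206). Erythroid genes rose (7 of 7 positive, median 3.58, 2.14e-06, and adjusted p = 0.517 with an estimated correlation), led by the haem synthesis gene Alas2, which rose from 123 ± 87.5 to 4138 ± 4024 (list-alone adjusted p = 0.0265, 0.989 over all genes). Mature neuron (22 of 25 positive, 1.3e-05), astrocyte (17 of 20, 0.000971), mature oligodendrocyte (18 of 18, 0.00181) and immediate early and dissection stress genes (17 of 18, 0.000491) rose as lists. With an estimated correlation the adjusted p was 0.587 for the oligodendrocyte list and 0.517 for the other 3. Mural and fibroblast genes fell (10 of 17 negative, 0.0116, and adjusted p = 0.517 with an estimated correlation), with Col1a1 at 1625 ± 1199 against 6013 ± 3058. Limma called 0 members of the neuron, astrocyte, mural, and immediate early and dissection stress lists by either adjustment (3, 1, 4 and 2 at an unadjusted p under 0.05) and 0 of the oligodendrocyte list (1 at an unadjusted p under 0.05, and 2 past the threshold in the authors' deposited table). The oligodendrocyte call was lost without ATRXfl_G34R replicate 3 (0.128) or p53_G34R replicate 2 (0.119), the astrocyte call without ATRXfl_G34R replicate 3 (0.0592) and the immediate early and dissection stress call without p53_G34R replicate 2 (0.0996). The mural call was lost without ATRXfl_G34R replicate 3 (0.0976) or p53_G34R replicate 3 (0.0842). ATRXfl_G34R replicate 3 is the tumour with the high Snap25 and Mobp counts.

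Interferon genes (28 of 28 positive, adjusted p = 0.00444), antigen presentation genes (17 of 18, 0.0162) and endothelial genes (16 of 17, 0.0415) also rose as lists, with an adjusted p = 0.698 with an estimated correlation for interferon and antigen presentation genes and 0.587 for endothelial genes. Limma called 0 of their members by either adjustment (0, 0 and 0 at an unadjusted p under 0.05). The interferon call was lost without ATRXfl_G34R replicate 3 (0.0592), ATRXfl_G34R replicate 4 (0.152) or p53_G34R replicate 2 (0.498, direction turned) and the antigen presentation call without ATRXfl_G34R replicate 3 (0.275), ATRXfl_G34R replicate 4 (0.144) or p53_G34R replicate 2 (0.153, direction turned). The endothelial call was lost without ATRXfl_G34R replicate 1 (0.0980), ATRXfl_G34R replicate 2 (0.165), p53_G34R replicate 1 (0.826) or p53_G34R replicate 2 (0.0662). Neuronal fate (0.172), ventral forebrain (0.629), dorsal forebrain (0.497), oligodendrocyte progenitor (0.270), cell cycle (0.218), hypoxia (0.0741) and microglia and macrophage genes (0.669) did not pass, and the neuronal fate list passed without ATRXfl_G34R replicate 4 (0.00640).

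Limma called 4 of 17459 genes for Atrx status with H3.3G34R: Dll3, Selenov and Adcy8, higher, and Gm11942, lower (7.07 ± 1.53 against 612 ± 581; chromosome 4, 32964888 to 32965232). Gm11942 was named after its values were seen and is uncertain, since a pseudogene can share reads with near-identical copies. At an unadjusted p under 0.05 there were 591 genes, and edgeR called 0 and DESeq2 113. Limma called 0 genes without any 1 of ATRXfl_G34R replicates 1 to 4 or p53_G34R replicates 2 and 3, with Xist as a covariate, or with libraries that share a title code summed, and 5 without p53_G34R replicate 1, Selenov and Gm11942 among them. The authors' deposited table has 113 genes past the threshold, 78 higher and 35 lower. Of DESeq2 calls in simulated data of this comparison, 61 of 173 were false. Chosen after their values were seen, genes past the threshold in the authors' deposited table include the neuronal enolase gene Eno2 (log2 1.99, adjusted p = 1.74e-08), Kctd8 (3.43, adjusted p = 5.72e-08) and the myeloid receptor gene Csf2ra (-1.84, adjusted p = 5.55e-05). In normalized counts Eno2 stood at 5179 ± 1194 against 1308 ± 125 and Csf2ra at 599.7 ± 167 against 2140.3 ± 384 (limma adjusted p = 0.0537 and 0.164). Groups did not overlap for 4.64% of genes, where chance gives 5.71%.

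With H3.3WT, Atrx-floxed tumours were compared with Atrx-intact tumours (n = 4 each). Selenov rose from 14.2 ± 8.87 to 815 ± 386 (log2 5.97 (SE 0.68), limma adjusted p = 0.0288), and it did not pass without any 1 of ATRXfl_WT replicates 1 to 4 or p53_WT replicates 2 and 4 (0.0596 to 0.234). Dll3 was at 20862 ± 7314 against 1822 ± 1201 with groups that did not overlap, and it did not pass (log2 4.26 (SE 1.003), adjusted p = 0.975). Its p53_WT replicate 3 held 87.2 counts and the other 3 tumours of that group 1936 to 2620.3, and without that library Dll3 passed (adjusted p = 0.0249). Adcy8, chosen here after its values were seen, was at 155 ± 25.7 against 265 ± 223 (log2 -0.26 (SE 0.70)). Notch pathway genes rose as a list, with 31 of 36 positive (median 0.46, camera adjusted p = 4.76e-05, and adjusted p = 0.430 with an estimated correlation), and the list passed without any 1 library. Without p53_WT replicate 3, 24 of 36 were positive, with a median of 0.39. The target gene Hes1 stood at 1089 ± 374 against 635 ± 236 and the receptor gene Notch3 at 2773 ± 2444 against 973 ± 449.7. Limma called 0 Notch members over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, and 1 past the threshold in the authors' deposited table).

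PRC2-bound developmental regulators rose as a list in Atrx-floxed against Atrx-intact tumours with H3.3WT (56 of 82 positive, median 0.73, adjusted p = 0.0114), as did Hox genes (7 of 8, median 1.86, 0.0298). Both had an adjusted p = 0.767 with an estimated correlation. Limma called 0 of their members by either adjustment (7 and 0 at an unadjusted p under 0.05). Gbx2, a gene of the midbrain and hindbrain boundary, was at 69.5 ± 61.9 against 10.8 ± 7.90. Hoxa5 was at 282 ± 201 against 332 ± 609 with a log2 change of 2.60 (SE 1.88), so that its means and its log2 change differ in sign, and the intact group spans 0 to 1234. The PRC2-bound call was lost without ATRXfl_WT replicate 1 (0.204), ATRXfl_WT replicate 2 (0.0557) or p53_WT replicate 3 (0.166), and the Hox call without ATRXfl_WT replicate 1 (0.0513), ATRXfl_WT replicate 2 (0.0720), p53_WT replicate 1 (0.144) or p53_WT replicate 3 (0.555). In p53_WT replicate 3, Hox genes had a median log2 difference of -5.33 from the other 3 tumours of the group (7 of 8 lower), and without it the median Hox change was 0.44. The authors' deposited table has log2 changes of 0.17 for Hoxa2, 0.41 for Hoxa3, -0.23 for Hoxa5 and 0.99 for Hoxa7, none past the threshold.

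Mature neuron (24 of 25 negative, adjusted p = 4.88e-06), neuronal fate (28 of 39, 0.00363) and dorsal forebrain genes (14 of 16, 0.00162) fell as lists, each with an adjusted p = 0.767 with an estimated correlation. Limma called 0 neuron or neuronal fate genes by either adjustment (1 and 3 at an unadjusted p under 0.05). The neuron call was lost without p53_WT replicate 3 (0.166), the neuronal fate call without ATRXfl_WT replicate 2 (0.0693) or p53_WT replicate 3 (0.251) and the dorsal call without p53_WT replicate 3 (0.646), the library rich in Snap25 and Mobp being p53_WT replicate 3. Without it the 3 medians moved from -2.17, -0.59 and -1.44 to -0.53, -0.32 and 0.19. The dorsal median then covered 11 tested genes instead of 16, since some members fell under the filter on low values. Bhlhe22, a transcription factor gene of cortical projection neurons, fell from 676 ± 418 to 60.2 ± 13.0 (log2 -3.25 (SE 0.51), limma adjusted p = 0.00186 over the list alone and 0.231 over all genes). Cell cycle genes fell (29 of 30 negative, median -0.54, 0.00162), while endothelial (15 of 17 positive, 0.00162), interferon (26 of 28, 0.00248), hypoxia (15 of 17, 0.0114) and immediate early and dissection stress genes (14 of 18, 0.0419) rose. With an estimated correlation each of these 5 lists had an adjusted p = 0.767. Pcna stood at 1189 ± 487 against 2135 ± 1023 and the endothelial receptor gene Robo4 at 1996 ± 2003 against 563 ± 227. Limma called 0 members of these 5 lists by either adjustment (0, 1, 0, 1 and 0 at an unadjusted p under 0.05). The cell cycle call was lost without ATRXfl_WT replicate 1 (0.314) or p53_WT replicate 2 (0.613), the endothelial call without ATRXfl_WT replicate 1 (0.314) or p53_WT replicate 2 (0.0540) and the interferon call without ATRXfl_WT replicate 4 (0.712), p53_WT replicate 1 (0.0820) or p53_WT replicate 2 (0.431). Without p53_WT replicate 3 the cell cycle median was -1.03. The hypoxia call was lost without ATRXfl_WT replicate 2 (0.0557), ATRXfl_WT replicate 3 (0.0552), ATRXfl_WT replicate 4 (0.172) or p53_WT replicate 1 (0.552), and the immediate early and dissection stress call without ATRXfl_WT replicate 1 (0.663), p53_WT replicate 1 (0.274), p53_WT replicate 2 (0.0856) or p53_WT replicate 3 (0.184).

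Limma called 6 of 17893 genes for Atrx status with H3.3WT, 3 higher and 3 lower, with 673 at an unadjusted p under 0.05, while edgeR called 2 and DESeq2 74. Apart from Selenov they were pseudogenes or predicted genes, named after their values were seen. Gm13394 rose from 2.33 ± 2.26 to 1932 ± 644 (log2 9.42 (SE 0.62), adjusted p = 0.00141) and Tdpx-ps1 rose from 3.11 ± 1.41 to 115 ± 46.5. With H3.3G34R and scaled over all 15 libraries, Gm13394 was at 2302 ± 903 in floxed and 289 ± 393 in intact tumours (3.46 to 738). Limma did not call Gm13394 in that comparison. Gm11942 fell from 515 ± 213 to 4.22 ± 2.72 (log2 -6.68 (SE 0.53)), and Gm18234 and Gm3650 also fell (adjusted p = 0.0221 and 0.0244). Near-identical copies can share the reads of such genes, so these values are uncertain. The count was 2, Gm13394 and Gm11942, without any 1 of ATRXfl_WT replicates 1 to 4 or p53_WT replicates 2 and 4, with Xist as a covariate, or with libraries that share a title code summed. It was 3 without p53_WT replicate 1 and 8 without p53_WT replicate 3, Dll3 then among them. The authors' deposited table has 74 genes past the threshold, 34 higher and 40 lower. Of DESeq2 calls in simulated data of this comparison, 63 of 157 were false. Chosen after their values were seen, genes past the threshold in the authors' deposited table include Strc (log2 6.95, adjusted p = 5.02e-09), Megf6 (2.97, adjusted p = 0.000341), Eid2 (1.34, adjusted p = 5.93e-06) and Dll3 (3.52, adjusted p = 0.00493). Groups did not overlap for 2.65% of genes, where chance gives 2.86%.

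Tumours with both changes, Atrx-floxed with H3.3G34R, were compared with tumours with neither (n = 4 each). Selenov rose from 13.6 ± 8.49 to 736 ± 323 (log2 5.87 (SE 0.67), limma adjusted p = 0.0483), and it did not pass without any 1 of ATRXfl_G34R replicates 1 to 4 or p53_WT replicates 2 and 4 (0.109 to 0.259). Adjusted over the Notch list alone, the target gene Hes1, a repressor of neuronal differentiation, rose from 612 ± 229 to 1416 ± 279 and Dll3 rose from 1757 ± 1158 to 22081 ± 10302 (adjusted p = 0.0403 for each, and 0.887 and 0.923 over all genes). The Notch list did not pass (23 of 36 positive, 0.0587). Without p53_WT replicate 3 Dll3 passed over all genes (0.0382), and the Notch list passed without ATRXfl_G34R replicate 4 (0.00633) or p53_WT replicate 1 (0.0223). Hox genes rose as a list (9 of 9 positive, median 3.09, 5.84e-05, and adjusted p = 0.898 with an estimated correlation), with Hoxa7 at 607 ± 469 against 153 ± 299. Without p53_WT replicate 3, where Hox genes lay lower than in the other 3, the Hox list passed (0.00907) with 9 of 9 positive and a median of 1.65. The authors' deposited table has 1.40 for Hoxa2, 1.31 for Hoxa3, 1.14 for Hoxa5 and 1.99 for Hoxa7, none past the threshold. Interferon (28 of 28 positive, 5.84e-05), antigen presentation (18 of 18, 4.23e-05), immediate early and dissection stress (18 of 18, 3.46e-06), hypoxia (17 of 17, 0.000641) and endothelial genes (13 of 17, 0.00823) rose, and dorsal forebrain genes fell (13 of 15 negative, 0.0172). With an estimated correlation each of these 6 lists had an adjusted p = 0.898. The interferon-induced gene Ifi27 stood at 6923 ± 2497 against 3298 ± 1566, the peptide transporter gene Tap2 at 2018 ± 672 against 1139 ± 568 and the early response gene Jun at 12335 ± 5678 against 4703 ± 1528. Limma called 0 members of the Hox list and these 6 lists over all genes or adjusted over the list alone (3, 2, 0, 3, 1, 0 and 0 at an unadjusted p under 0.05).

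The interferon call for both changes against neither was lost without p53_WT replicate 2 (0.132), the hypoxia call without ATRXfl_G34R replicate 4 (0.0505) or p53_WT replicate 1 (0.254) and the endothelial call without p53_WT replicate 1 (0.0630), p53_WT replicate 2 (0.285) or p53_WT replicate 4 (0.0786). The dorsal forebrain call was lost without ATRXfl_G34R replicate 4 (0.0665) or p53_WT replicate 3 (0.918, direction turned). Without p53_WT replicate 3 the median moved from -1.42 (15 tested genes) to 0.04 (11 tested genes). Mature neuron genes (0.128), neuronal fate genes (0.649), PRC2-bound regulators (0.118) and cell cycle genes (0.732) did not pass. The mature neuron list passed without ATRXfl_G34R replicate 3 (0.0109), p53_WT replicate 1 (0.0328), p53_WT replicate 2 (0.000267) or p53_WT replicate 3 (0.00786, direction turned), and the PRC2-bound list without ATRXfl_G34R replicate 3 (0.0186) or p53_WT replicate 1 (0.0375). The authors' deposited table has 4 members of the PRC2-bound list and 1 of the Notch list past the threshold. Limma called 4 of 17659 genes, with 772 at an unadjusted p under 0.05, while edgeR called 2 and DESeq2 77. Beside Selenov, and named after their values were seen, these were Gm13394 (2231 ± 870.5 against 2.24 ± 2.18) and Tdpx-ps1 (93.1 ± 34.8 against 2.99 ± 1.36), higher, and Gm11942 (6.85 ± 1.48 against 495 ± 202), lower, all uncertain as pseudogenes. The count was 2, Gm13394 and Gm11942, without any 1 of ATRXfl_G34R replicates 1 to 3 or p53_WT replicates 2 and 4. It was 3 without ATRXfl_G34R replicate 4 or p53_WT replicate 1, and 8 without p53_WT replicate 3. The authors' deposited table has 77 genes past the threshold, 45 higher and 32 lower. Of DESeq2 calls in simulated data of this comparison, 59 of 164 were false. Chosen after their values were seen, genes past the threshold in the authors' deposited table include the cytokine gene Il6 (log2 5.26, adjusted p = 2.67e-06), Micall2 (2.04, adjusted p = 0.00207) and the gelatinase gene Mmp2 (-3.31, adjusted p = 0.000733). Mmp2 passed limma without p53_WT replicate 3 (0.0248). Groups did not overlap for 2.94% of genes, where chance gives 2.86%.

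Whether H3.3G34R acted differently with Atrx floxed than with Atrx intact was tested as an interaction over all 15 libraries. Mature neuron genes had 25 of 25 positive interactions (median log2 3.02, camera adjusted p = 2.15e-11, and adjusted p = 0.574 with an estimated correlation), the median change with H3.3G34R being 1.40 when Atrx was floxed and -1.11 when it was intact. The value in intact tumours rests on p53_WT replicate 3, the library rich in Snap25 and Mobp, and without it was 0.04 (13 of 25 positive), with a median interaction of 1.66. Neuronal fate genes (31 of 39 positive, 0.000437) and dorsal forebrain genes (14 of 16, 0.000670) had positive interactions and Notch genes a negative one (31 of 36 negative, median -0.45, 0.000626). With an estimated correlation the neuronal fate and dorsal lists had an adjusted p = 0.574 and the Notch list 0.340. By limma, 0 members of the 4 lists passed by either adjustment (4, 0, 2 and 1 at an unadjusted p under 0.05). The dorsal forebrain call was lost without p53_WT replicate 3 (0.312), where the median went from 1.62 to 0.21, and without the same library the mature neuron, neuronal fate and Notch lists passed (4.18e-05, 0.0255 and 0.00316). Hox genes (6 of 8 positive, 0.550) and PRC2-bound regulators (27 of 80, 0.279) did not pass, and the Hox list passed without p53_WT replicate 3 (0.00573).

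Mature oligodendrocyte (15 of 18 positive, adjusted p = 0.00190), astrocyte (17 of 20, 0.00193), erythroid (7 of 7, 0.0170) and cell cycle genes (29 of 30, 0.000234) had positive interactions, and mural (15 of 17 negative, 0.00149) and hypoxia genes (16 of 17, 0.00119) negative ones. With an estimated correlation the adjusted p was 0.574 for oligodendrocyte, astrocyte and mural genes, 0.678 for erythroid, 0.682 for cell cycle and 0.640 for hypoxia genes. By limma, 0 members of these 6 lists passed by either adjustment (0, 1, 0, 0, 2 and 2 at an unadjusted p under 0.05). The oligodendrocyte call was lost without ATRXfl_G34R replicate 3 (0.102) or p53_WT replicate 3 (0.0682), the astrocyte call without ATRXfl_G34R replicate 3 (0.0582) or p53_WT replicate 3 (0.225) and the cell cycle call without ATRXfl_WT replicate 1 (0.0576) or p53_WT replicate 2 (0.185). Without p53_WT replicate 3 the median interaction went from 1.07 to 0.27 for astrocyte genes and from 0.66 to 1.19 for cell cycle genes. The mural call was lost without ATRXfl_WT replicate 1 (0.168). The hypoxia call was lost without p53_G34R replicate 1 (0.809) or p53_WT replicate 1 (0.0984), and the erythroid call without ATRXfl_G34R replicate 2 (0.0765), ATRXfl_G34R replicate 4 (0.0887), ATRXfl_WT replicate 2 (0.0958), ATRXfl_WT replicate 4 (0.116), p53_G34R replicate 3 (0.250), p53_WT replicate 1 (0.284) or p53_WT replicate 4 (0.0901). Limma called 0 of 17776 genes for the interaction, with 365 at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 10. In simulated data of the interaction, limma recovered 59.1% of genes changed 8-fold, 11.9% of those changed 4-fold and 0% of those changed 2-fold. Adcy8, chosen after its values were seen, had an interaction of log2 3.55 (SE 0.83) (limma adjusted p = 0.9996), with 509.8 and 394 counts in p53_WT replicates 1 and 3 and at most 97.6 in the other 2. Selenov had an interaction of -0.76 (SE 0.91) and Dll3 of -0.77 (SE 1.22).

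Log2 changes for H3.3G34R in floxed and in intact tumours, comparisons that share no library, had a Pearson r of -0.09 across 17029 genes, which are not independent replicates, and 51.0% of genes had the same sign. That share ranged from 46.3% (without ATRXfl_G34R replicate 4) to 54.7% (without ATRXfl_G34R replicate 3). A count of 0 genes passed in both of the authors' deposited tables. Log2 changes for Atrx status with H3.3G34R and with H3.3WT had r = 0.14 across 17092 genes, and 55.1% had the same sign. In the authors' deposited tables, 7 genes were higher in both Atrx comparisons, where independent lists would share 0.0886, and 8 were lower in both, where independent lists would share 0.0592. In the authors' deposited tables these include Dll3, Selenov, Fbl and the predicted gene Gm45011, higher, and Atrx and Gm11942, lower. Gm45011 was named after its values were seen. Selenov, Fbl and Gm45011 lie within 250 kb of Dll3 on chromosome 7, so the overlap of independent lists is not a measure for these neighbours.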

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

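The explanations of the Dll3 neighbourhood and of p53_WT replicate 3 in this part were chosen for testing after those results were seen. Libraries far from the others of their group were looked for in 39 measures over the 3 groups of 4, where chance marks about 1 in 20 groups. Of 117, 15 were marked because the gap from 1 library to the nearest other exceeded Dixon's 95% critical share of the group's whole range. In normalized counts, the engineered growth factor gene Pdgfa had 12198 against 26085 to 28476 in the other 3 in ATRXfl_WT replicate 1. Gm13394 had 3651 against 1731 to 1921 in the other 3 in ATRXfl_G34R replicate 4, and Gm3650 had 50.5 against 0 to 0.987 in the other 3 in ATRXfl_G34R replicate 1. Gm18234 had 32.1 against 0 to 1.21 in the other 3 in ATRXfl_G34R replicate 1, 0.871 against 0 in the other 3 in ATRXfl_WT replicate 3 and 128 against 56.4 to 58.5 in the other 3 in p53_WT replicate 4. As the mean log2 of a list, Notch pathway genes stood at 9.84 against 10.17 to 10.23 in the other 3 in ATRXfl_G34R replicate 4 and 9.58 against 9.83 to 9.88 in the other 3 in p53_WT replicate 3. In ATRXfl_WT replicate 2, dorsal forebrain genes stood at 5.37 against 4.97 to 5.02 in the other 3 and oligodendrocyte progenitor genes at 12.94 against 13.84 to 13.98 in the other 3. Interferon genes stood at 8.05 against 10.17 to 10.58 in the other 3 in ATRXfl_G34R replicate 2. Hypoxia genes stood at 9.56 against 10.70 to 10.91 in the other 3 and immediate early and dissection stress genes at 11.36 against 9.63 to 9.81 in the other 3 in ATRXfl_WT replicate 1. Ependymal genes stood at 6.77 against 5.71 to 5.87 in the other 3 in p53_WT replicate 3.

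p53_WT replicate 3 was also marked for its read total, 35679129 against 24979735 to 25377285 in the other 3 of the group, the highest of all 15 libraries. Against the mean of the other 3 tumours, its mature neuron, mature oligodendrocyte and astrocyte genes had median log2 differences of 5.81, 3.95 and 2.33, so each of the 3 lists lay at least 2.33 higher, while Pdgfa (-4.30), its receptor gene Pdgfra (-4.09) and the progenitor factor gene Olig2 (-2.91) lay lower. That is what normal cortex in the specimen would give. Neuronal differentiation of the tumour cells alone was excluded, since it would leave astrocyte and mature oligodendrocyte genes within 1 log2 unit and the lower of the 2 was 2.33 higher, and a low read total was excluded at 35679129 reads. Differentiation of tumour cells into all 3 cell types was not tested.

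Within 250 kb of Dll3 on chromosome 7, all 19 tested neighbours had median log2 changes of 0.43 with H3.3G34R and 0.96 with H3.3WT in Atrx-floxed tumours, and 15 were higher in both. The 13 that neither deposited table calls stood out in neither comparison alone. Their median log2 change was 0.24 (SE 0.14) with H3.3G34R and 0.02 (SE 0.18) with H3.3WT. They were set against 16390 windows, all runs of 13 consecutive such genes on a chromosome, leaving out genes within 10 Mb of Dll3. These windows overlap each other and were not limited to 250 kb. Of them, 6.18% and 44.5% had a median as high, although 4.42% were as high in both. Because called genes were left out of the windows, the test cannot tell whether a local change came with the Atrx-floxed mouse line, and loss of Atrx and the mouse line that carries the floxed gene cannot be told apart, since every floxed tumour comes from that line. A gain in every cell of the floxed tumours that covers most of the tested genes 1 to 10 Mb from Dll3 was excluded. The median there was -0.0498 (SE 0.05) in H3.3G34R tumours over 226 genes, under the 0.58 that 1 extra copy gives. A gain in a few cells, one that covers a smaller share of those genes, or one nearer to Dll3 only, was not excluded. The median of the 35 other Notch members did not rise by at least 1 log2 unit in both comparisons, being -0.00162 with H3.3G34R. That bar was set after the values were seen, so it excludes neither a smaller rise nor a rise of some members. With H3.3WT the median of those members was 0.46 (SE 0.11) and the list passed.

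The change with H3.3G34R differed between Atrx-floxed and Atrx-intact tumours for 11 lists by the camera test of the interaction, whose p-values and single-library dependence are given with that comparison or, for choroid plexus genes, among the other observations. The difference in log2 change, as the median of the list and with the value without p53_WT replicate 3 in parentheses, was -0.45 (-0.37) for Notch pathway genes, 0.70 (0.47) for neuronal fate genes, 1.62 (0.21) for dorsal forebrain genes, 3.02 (1.66) for mature neuron genes, 0.52 (0.60) for mature oligodendrocyte genes, 1.07 (0.27) for astrocyte genes, 1.35 (0.60) for choroid plexus genes, -1.36 (-1.28) for mural genes, 2.61 (3.92) for erythroid genes, 0.66 (1.19) for cell cycle genes and -0.64 (-0.68) for hypoxia genes. The dorsal forebrain values cover 16 tested genes with p53_WT replicate 3 and 12 without it. None of the 11 lists passed with an estimated correlation (adjusted p = 0.340 to 0.682).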

How the results depend on the processing

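TMM scaling was added as an alternative after the data were seen. The edgeR test was named beforehand as an added alternative and is counted apart, and the other settings were fixed before. For H3.3G34R with Atrx floxed, H3.3G34R with Atrx intact and the interaction, limma called 0 genes in the reported analysis and under each alternative but DESeq2 (488, 262 and 365 at an unadjusted p under 0.05), edgeR called 0 in each, and DESeq2 called 34, 12 and 10. For Atrx status with H3.3G34R the count of 4 became 12 without the filter on low values, 113 by DESeq2, 0 by edgeR (644 at an unadjusted p under 0.05), 0 with libraries that share a title code summed and 0 with Xist as a covariate, and was 3 to 5 under the others. For Atrx status with H3.3WT the 6 became 2 by edgeR, 74 by DESeq2, 2 with libraries summed and 2 with the covariate, and was 5 to 7 under the others. For both changes against neither the 4 became 2 with a pseudocount of 0.5, 2 by edgeR, 77 by DESeq2, 2 with libraries summed and 2 with the covariate, and was 3 to 5 under the others. Leaving out 1 library gave 0 to 5, 2 to 8 and 2 to 8 genes in these 3 comparisons. The share of genes with the same sign of H3.3G34R change in floxed and intact tumours was 46.3% to 54.7% without 1 library, against 51.0%. The cause of each change was not tested.

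Of 63 list calls among the lists described, 63 held with TMM and with either pseudocount, 56 without the filter, 58 with the Xist covariate, 52 with libraries summed, 46 of 52 with 4 groups in 1 fit, 13 without any 1 library and 0 with an estimated correlation. Of 87 lists that did not pass, 19 passed with libraries summed, 13 with the covariate, 5 without the filter and 62 without some 1 library. The calls lost without the filter were endothelial and choroid plexus genes for H3.3G34R with Atrx floxed, neutrophil genes for H3.3G34R with Atrx intact, DNA repair genes for Atrx status with H3.3G34R, Hox and PRC2-bound genes for Atrx status with H3.3WT and choroid plexus genes for the interaction. With the covariate they were endothelial genes for Atrx status with H3.3G34R, Hox and immediate early and dissection stress genes for Atrx status with H3.3WT and dorsal forebrain and hypoxia genes for both changes against neither. With libraries summed they were endothelial and antigen presentation genes for H3.3G34R with Atrx floxed, mural, interferon, antigen presentation, immediate early and dissection stress, ependymal and DNA repair genes for Atrx status with H3.3G34R, Hox and PRC2-bound genes for Atrx status with H3.3WT and dorsal forebrain genes for both changes against neither. With 4 groups in 1 fit they were antigen presentation genes for H3.3G34R with Atrx floxed, endothelial and B cell genes for Atrx status with H3.3G34R, immediate early and dissection stress genes for Atrx status with H3.3WT and endothelial and B cell genes for both changes against neither. Lists were not run with edgeR, DESeq2 or voom.

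The direction of a list that passed before or after turned in 19 of 2348 list results under the alternatives fixed before, and that of a list that passed neither time in 146 more. The former are given here as the adjusted p and, where 1 library was left out, its range over libraries. For H3.3G34R with Atrx floxed it turned for microglia genes (0.0468 without ATRXfl_WT replicate 1, range 0.0151 to 0.950), endothelial genes (0.211 without ATRXfl_WT replicate 1, range 0.000172 to 0.211) and antigen presentation genes (0.727 without ATRXfl_WT replicate 3, range 3.12e-06 to 0.727). For H3.3G34R with Atrx intact it turned for interferon genes (0.0452 without p53_G34R replicate 1, range 3.58e-06 to 0.974), oligodendrocyte progenitor genes (0.0450 without p53_WT replicate 3, range 0.000140 to 0.415) and DNA repair genes (0.00622 without p53_WT replicate 3, range 0.00622 to 0.989). For Atrx status with H3.3G34R it turned for interferon genes (0.900 with libraries summed and 0.498 without p53_G34R replicate 2, range 4.2e-10 to 0.498), antigen presentation genes (0.906 with libraries summed and 0.153 without p53_G34R replicate 2, range 9.77e-07 to 0.275) and hypoxia genes (0.0169 without p53_G34R replicate 1, range 0.000674 to 0.582). For Atrx status with H3.3WT it turned for oligodendrocyte progenitor genes (0.00319 without p53_WT replicate 3, range 0.00319 to 0.712). For both changes against neither it turned for dorsal forebrain genes (0.918 without p53_WT replicate 3, range 0.000267 to 0.918), mature neuron genes (0.00786 without p53_WT replicate 3, range 0.000267 to 0.514), oligodendrocyte progenitor genes (0.00683 without p53_WT replicate 3, range 0.000728 to 0.448) and cell cycle genes (0.00844 without p53_WT replicate 2, range 3.17e-06 to 0.890). For the interaction it turned for antigen presentation genes (0.0163 with libraries summed and 0.0181 without p53_G34R replicate 2, range 0.0181 to 0.956) and oligodendrocyte progenitor genes (0.0482 without p53_WT replicate 3, range 0.00150 to 0.528). The cause was not tested. Of 1395 values of named genes under the same alternatives, 7 had the opposite sign, none of a gene that passed before or after, while 96 lost and 42 gained a call. Hoxa5 for Atrx status with H3.3WT had a log2 change of -0.23 by DESeq2 against 2.60 by limma. No paired analysis was possible because replicate numbers were given in the order of the library records and pair nothing. The main scaling is already the median-of-ratios method named as an alternative before, so that alternative is the reported analysis. At these read totals and group sizes, limma recovered 5.97% to 55.2% of simulated 4-fold changes in the 5 comparisons. Of DESeq2 calls in the simulated data, 67 of 192, 77 of 157, 61 of 173, 63 of 157 and 59 of 164 were false in the order of the report, against 6 of 95, 4 of 31, 8 of 82, 3 of 54 and 7 of 57 for limma.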

Other observations

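The 6 lists described first, and the DESeq2 splits of all but Atrx status with H3.3G34R, were chosen after the results were seen, while the other counts over splits of the libraries were planned before the data were examined. Some lists of immune cell genes differed between groups. Microglia and macrophage genes passed camera in no comparison with every library in the fit (adjusted p = 0.669 to 0.913). T and NK cell genes rose by camera with H3.3G34R in Atrx-floxed tumours (13 of 16 positive, median log2 change 0.59, adjusted p = 0.00405, and adjusted p = 0.852 with an estimated correlation), with the T cell receptor partner gene Cd8a at 47.3 ± 28.2 against 10.7 ± 10.1 normalized counts (n = 4 each). They also rose in Atrx-floxed against Atrx-intact tumours with H3.3G34R (13 of 16, 0.00555, and adjusted p = 0.517 with an estimated correlation) and with both changes against neither (12 of 17, 0.00823, and adjusted p = 0.898 with an estimated correlation), with the interleukin receptor gene Il2rb at 81.0 ± 30.5 against 22.8 ± 16.3 in the latter. These 3 calls were lost, in that order, without ATRXfl_G34R replicate 3 (0.0924), ATRXfl_G34R replicate 4 (0.0635), ATRXfl_WT replicate 2 (0.0514) or ATRXfl_WT replicate 3 (0.158), without ATRXfl_G34R replicate 3 (0.0785), ATRXfl_G34R replicate 4 (0.0857), p53_G34R replicate 1 (0.0579) or p53_G34R replicate 2 (0.226) and without ATRXfl_G34R replicate 3 (0.0598), ATRXfl_G34R replicate 4 (0.125), p53_WT replicate 2 (0.218) or p53_WT replicate 3 (0.0933). B cell genes rose in Atrx-floxed against Atrx-intact tumours with H3.3G34R (7 of 7 positive, adjusted p = 0.0162, and adjusted p = 0.517 with an estimated correlation) and with both changes against neither (6 of 7, 0.0252, and adjusted p = 0.898 with an estimated correlation). These calls were lost without ATRXfl_G34R replicate 3 (0.0592), ATRXfl_G34R replicate 4 (0.241), p53_G34R replicate 2 (0.0629) or p53_G34R replicate 3 (0.161), and without ATRXfl_G34R replicate 3 (0.0615), p53_WT replicate 2 (0.428), p53_WT replicate 3 (0.0685) or p53_WT replicate 4 (0.0689). Adjusted over the list alone, the immunoglobulin genes Jchain and Igkc passed limma in the latter (adjusted p = 0.0269 and 0.0269, and 0.996 and 0.996 over all genes). Jchain rose from 18.9 ± 5.98 to 1635 ± 2904, with 6191 counts in ATRXfl_G34R replicate 4 and 109.8 to 341 in the other 3. Neutrophil genes rose with H3.3G34R in Atrx-intact tumours (7 of 7 positive, adjusted p = 0.0105, and adjusted p = 0.862 with an estimated correlation), with the gelatinase gene Mmp9 at 1828 ± 920.0 against 348 ± 441 (list-alone adjusted p = 0.0680), and that call was lost without p53_G34R replicate 1 (0.369), p53_WT replicate 2 (0.0548) or p53_WT replicate 3 (0.0910).

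Genes of DNA damage repair and telomeres fell as a list in Atrx-floxed against Atrx-intact tumours, both with H3.3G34R (24 of 31 negative, median -0.14, adjusted p = 0.0116, and adjusted p = 0.517 with an estimated correlation) and with H3.3WT (24 of 31, median -0.41, 0.00162, and adjusted p = 0.767 with an estimated correlation). The shelterin gene Acd was at 1303 ± 184 against 1721 ± 244 with H3.3G34R and 1219 ± 272 against 1681 ± 499 with H3.3WT. Limma called 0 members with H3.3G34R (0 at an unadjusted p under 0.05) and 0 with H3.3WT (1 at an unadjusted p under 0.05) by either adjustment, and edgeR called 0. The calls were lost without ATRXfl_G34R replicate 3 (0.0592), p53_G34R replicate 2 (0.119) or p53_G34R replicate 3 (0.209) with H3.3G34R, and without ATRXfl_WT replicate 1 (0.0513), ATRXfl_WT replicate 2 (0.0584) or p53_WT replicate 2 (0.202) with H3.3WT. Choroid plexus genes rose with H3.3G34R in Atrx-floxed tumours (6 of 6 positive, 0.0190, and adjusted p = 0.852 with an estimated correlation), with the water channel gene Aqp1 at 184 ± 220.3 against 67.1 ± 85.8, and had a positive interaction (4 of 5, 0.0242, and adjusted p = 0.340 with an estimated correlation). Those calls were lost without ATRXfl_G34R replicate 3 (0.416), ATRXfl_G34R replicate 4 (0.181), ATRXfl_WT replicate 3 (0.338) or ATRXfl_WT replicate 4 (0.0623), and for the interaction without ATRXfl_G34R replicate 4 (0.0615), ATRXfl_WT replicate 3 (0.0511), ATRXfl_WT replicate 4 (0.0562), p53_G34R replicate 1 (0.0882), p53_WT replicate 1 (0.0601) or p53_WT replicate 3 (0.103). In Atrx-intact tumours the choroid list did not pass (0.522), while Kl, a co-receptor for a fibroblast growth factor, fell from 62.5 ± 39.0 to 9.68 ± 3.56 with H3.3G34R (list-alone limma adjusted p = 0.0405, 0.99999 over all genes). Ependymal genes rose in Atrx-floxed against Atrx-intact tumours with H3.3G34R (8 of 9 positive, 0.0133, and adjusted p = 0.517 with an estimated correlation), with the dynein gene Dnah11 at 91.5 ± 64.7 against 31.4 ± 12.3, and the call was lost without ATRXfl_G34R replicate 3 (0.0855), p53_G34R replicate 1 (0.0579) or p53_G34R replicate 2 (0.185).

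Counts of genes past the threshold were set against those of other splits of the same libraries. For Atrx status with H3.3G34R, the real split ranked first by limma, with 4 genes against 3 in the highest other and 1 of 35 splits as high. For Atrx status with H3.3WT it ranked first too, with 6 genes in the real split, 1 in the highest other and 1 of 35 splits as high. If the libraries are independent, both met the rule fixed beforehand for an excess over chance. A share of 1 in 35 is the smallest that these splits can give. It was not adjusted for the number of split tests, so a first rank alone does not exclude chance. For both changes against neither, chance was not excluded, as 2 of 35 splits gave at least 4 genes and the highest other gave 6. For H3.3G34R with Atrx floxed, with Atrx intact and for the interaction, the limma count was 0, so each split counts as high (35 of 35, 35 of 35 and 100 of 100, 99 of them drawn beside the real one), with 1, 12 and 35 genes in the highest other split, while 488, 262 and 365 genes had an unadjusted p under 0.05, edgeR called 0 in each and DESeq2 called 34, 12 and 10. These splits treat the libraries as independent, and some share a title code. With such libraries summed, the 4 and 6 genes called for Atrx status with H3.3G34R and with H3.3WT became 0 and 2, and for H3.3G34R 2 other splits gave 3 genes and 6 of 7 fits without 1 library gave 0. By DESeq2, chance was excluded for none of the 5 comparisons. Among genes with a mean of at least 10 it called 27 (16 of 35 splits gave as many, the highest other 176) for H3.3G34R with Atrx floxed, 8 (35 of 35 splits gave as many, the highest other 558) for H3.3G34R with Atrx intact, 102 (9 of 35 splits gave as many, the highest other 511) for Atrx status with H3.3G34R, 69 (11 of 35 splits gave as many, the highest other 390) for Atrx status with H3.3WT and 81 (15 of 35 splits gave as many, the highest other 446) for both changes against neither. The highest other split gave several times the real count in each, as would come from a structure among the libraries other than the groups compared or from false calls. In simulated data of these comparisons, taken in that order, 67 of 192, 77 of 157, 61 of 173, 63 of 157 and 59 of 164 DESeq2 calls were false. Seen afterwards, for both changes against neither every split with 97 to 446 calls grouped ATRXfl_G34R replicate 3 with p53_WT replicate 3. No split that kept them apart gave more than 91. For Atrx status with H3.3G34R, every split with 147 to 511 calls grouped ATRXfl_G34R replicate 4 with p53_G34R replicate 1. That argues against false calls alone in these 2 comparisons, as such calls would not follow 1 pair of libraries. For the other comparisons, which of the 2 gave the high splits was not tested.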
